A study of Mus musculus with 12 samples.

How the data were processed

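RNA from pancreatic islets of male C57BL/6 mice was sequenced in 12 libraries, 3 each from wild type (WT) and beta-cell-selective Sirt3 knockout (KO) mice on a standard or a high fat diet. Per the labels, islets were isolated with collagenase and a density gradient, libraries were made from total RNA by Illumina protocols, and high fat feeding lasted 36 weeks after 4 weeks (WT) or 5 to 6 weeks (KO) of standard food. Genotype and this earlier period therefore differ together within the high fat groups.

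The authors deposited, for each library, read counts per gene as made by them from reads aligned to mm10, and FPKM values as deposited for the same genes. The labels name TopHat2, Cufflinks and DESeq without versions. Which of these made which file, the annotation release, the counting tool and the strand setting are not given in the sources used here. Each file listed 54532 Ensembl genes, of which 29339 had at least 1 count in some library. The deposited FPKM values equalled the count divided by gene length and library total for all 257939 nonzero values compared (relative tolerance 1e-05), so the FPKM hold the same measurement as the counts, with no further normalization. Symbols were joined by Ensembl ID (54409 found), and coordinates came from GENCODE M21 (54495 found); 203 symbols are shared by more than 1 ID.

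Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 16076, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion estimates was fitted with 1 mean per group, and 5 contrasts were tested: KO against WT under each diet, high fat against standard diet in each genotype, and the interaction. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05, and SEs came from the same fits. The common biological coefficient of variation was 0.307. Total counts of 16037709 to 20864920 per library gave a chi-square per degree of freedom between replicates of 27 to 105.4, so spread between libraries, not counting error, set the precision. Counting intervals of ratios (95%) cover counting error alone. Folds against a group without counts were taken against a floor of 3 counts over the group. On simulated data, 71 to 81 of 100 genes changed 4-fold and 28 to 39 of 100 changed 2-fold were recovered in the contrasts of 2 groups. False calls there made up 0.8% to 6.2% of calls. The simulation drew genes independently, without correlation between genes or trends with gene length. Its rates of false calls therefore need not hold for the real libraries.

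Gene lists were written from general knowledge of islet biology: 30 lists, for the sirtuin family; beta cell identity; alpha cell; delta, PP and epsilon cell; beta cell dedifferentiation and disallowed genes. Further lists covered serotonin synthesis, storage and receptors, the lactogen and STAT5 response of islets, cell cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, the tricarboxylic acid cycle and pyruvate entry, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, and glycolysis and hypoxia. The others covered the unfolded protein and integrated stress response, antioxidant defence, exocytosis and granule, macrophage and myeloid cell, lymphocyte, cytokine and NF-kappaB response, interferon response, immediate early and heat shock, acinar cell, ductal cell, endothelial cell, stellate cell, fibroblast and matrix, adipocyte, Schwann cell and neuron, and erythrocyte. Of the lactogen list, 5 genes (Tph1, Tph2, Socs3, Ehhadh and Chgb) also stand in another list. Lists were tested with camera from limma at a preset inter-gene correlation of 0.01, and again with the correlation estimated per list and with fry, each adjusted over the 30 lists. The camera test compares a list with the other genes, and fry tests it against no change.

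Samples, contrasts, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named 10 genes always (Sirt3, Tph1, Ins1, Ins2, Gcg, Sst, Ppy, Mafa, Slc2a2 and Aldh1a3). It added the 8 largest changes per direction among genes past the threshold with a mean of at least 2 CPM and no overlap between groups, leaving out predicted and small RNA genes, or the 3 smallest p-values where fewer than 3 passed. It also added up to 4 members past the threshold per list, or else up to 2 with the smallest p. Genes named outside it are said to be chosen after their values were seen.

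Alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no filter and a stricter filter (at least 1 CPM in 6 libraries), limma-trend on log2 FPKM with a pseudocount of 1 or 0.1 (mean FPKM of at least 0.5), a fit of the compared groups alone, the replicate number as a block, and leaving out each library in turn. Leaving out STD WT 3 and HFD KO 2 together, and offsets corrected for gene length with and without HFD KO 3, were added after the data were seen. The labels number the libraries of each group alike without saying what a number marks. The deviations of same-numbered HFD WT and HFD KO libraries from their group means correlated in all 3 pairs (r from 0.336 to 0.515; other numbers −0.382 to −0.028). In the other pairings of groups at most 1 of 3 same-numbered pairs exceeded 0.1. Differently numbered libraries correlated as strongly elsewhere, as STD WT 1 with HFD WT 2 (r = 0.518) and STD WT 3 with HFD WT 1 (0.416). The correlations thus do not show that equal numbers mark paired libraries. Because of the high fat pairs, the replicate number was also fitted as a block in the high fat groups alone, with and without length-corrected offsets. This was decided after the fits had been seen, from the correlations and not the labels. No library was left out of the reported values. Results of some single genes that the naming rule covers are not reported here; they stayed in all counts and list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.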

Results

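The transcriptome of pancreatic islets, the endocrine clusters that hold the insulin-producing beta cells, was measured by RNA sequencing in male C57BL/6 mice with a beta-cell-selective knockout of Sirt3 (KO) and in wild type mice (WT). Sirt3 encodes a mitochondrial NAD-dependent deacetylase. Animals of each genotype had received a standard diet with 6.2% fat (STD) or a high fat diet with 60% of calories from fat (HFD), the latter for 36 weeks, and all samples were labelled as taken at 40 weeks of age. The 12 libraries formed 4 groups of 3, named by diet, genotype and number. Total counts per library lay between 16037709 and 20864920, and 20386 to 22360 genes had at least 1 count. Insulin transcripts took a large share of every library: Ins2 made up 13.2% to 25.4% of counts and Ins1 6.41% to 11.9%. Within groups, log2 CPM, counts scaled to library size, correlated between libraries with r from 0.913 to 0.967 across genes. The labels did not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries.

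Sirt3 itself (ENSMUSG00000025486, mm10 chromosome 7, 140863666 to 140882309, minus strand) was measured first, as a check of the genotype labels. Under the standard diet it stood at 10.6 ± 1.37 CPM in WT and 6.14 ± 0.40 CPM in KO islets (SD, n = 3). Each of the KO libraries, at 6.59, 5.97 and 5.86 CPM, lay below the lowest WT library at 9.04 CPM. Under the high fat diet the means were 10.9 ± 1.36 CPM in WT and 8.53 ± 2.73 CPM in KO (SD, n = 3). HFD KO 1 and HFD KO 3 had 7.85 and 6.21 CPM, whereas the library labelled HFD KO 2 had 11.5 CPM, inside the WT range of 9.04 to 11.8 CPM. Neither difference passed the threshold in edgeR's quasi-likelihood test: the log2 fold change was −0.79 (SE 0.22, adjusted p = 0.156) under the standard diet and −0.35 (SE 0.22, adjusted p = 0.363) under the high fat diet. Counts cover the whole gene in all islet cell types, and the labels do not say which exons were deleted. Non-beta cells keep the gene, so this level is a weak check of the labels. None of the other 6 sirtuin genes passed the threshold either, and the sirtuin list as a group did not pass the camera set test under the standard (adjusted p = 0.147) or the high fat diet (adjusted p = 0.553). Adjusted over the list alone, 1 member was lower under the standard diet, Sirt3, and 0 of 7 under the high fat diet.

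**Figure D1:**
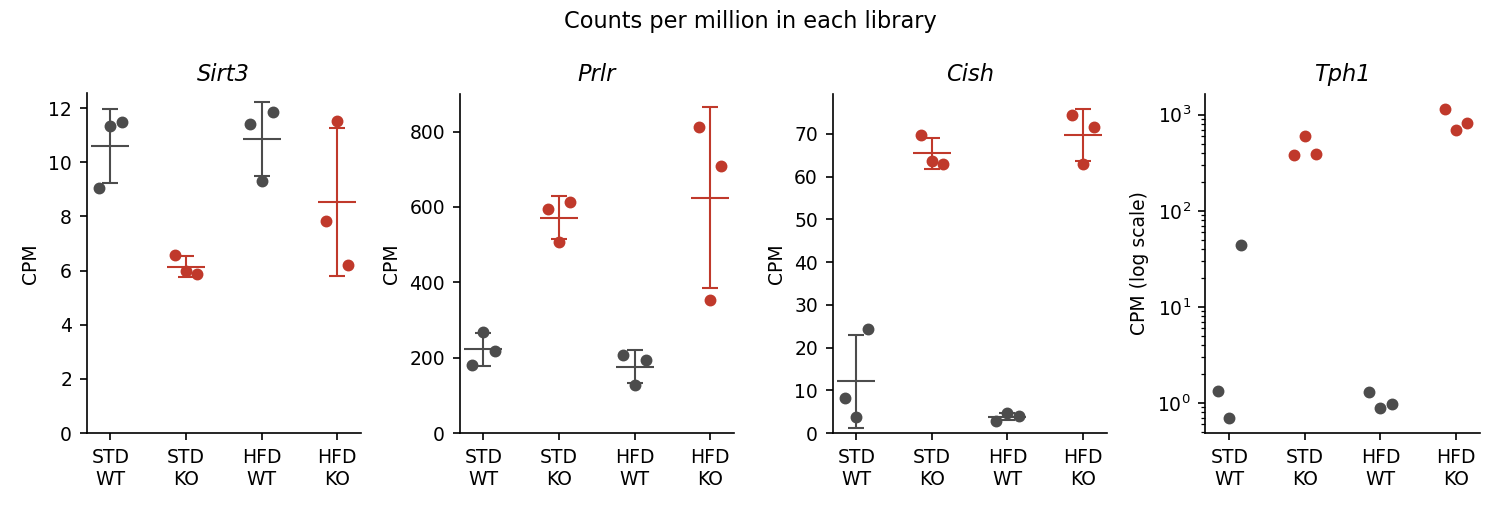
CPM of Sirt3, Prlr, Cish and Tph1 in each of the 12 libraries, by diet and genotype; bars show the group mean and SD of 3 libraries, and Tph1 is drawn on a log axis without bars. The Sirt3 level of the library labelled HFD KO 2 (11.5 CPM) lies among the WT libraries, while its Tph1 (701 CPM) lies among the KO libraries, and STD WT 3 has 43.5 CPM of Tph1.

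The first comparison asked how loss of Sirt3 in beta cells changed islet expression under a standard diet. The clearest group was the lactogen and STAT5 response of islets, the genes that prolactin and placental lactogen switch on in beta cells during pregnancy: 11 of 16 measured members rose in KO islets and none fell, with a median log2 fold change of 2.10. Matn2, a matrix protein, rose from 18.8 ± 7.58 to 322 ± 13.8 CPM (SD, n = 3). Neb (log2 fold change 3.94, SE 0.47, adjusted p = 0.00168), Gbp8 (3.80, SE 0.30, adjusted p = 7.48e-05) and the tryptophan hydroxylase gene Tph2 (3.64, SE 0.53, adjusted p = 0.00541) rose with it. Adjusted over the list alone, 12 members rose. The set test placed the list above the other genes with camera (adjusted p = 2.36e-27; adjusted p = 0.013 with an estimated correlation). Tested against no change with fry, its adjusted p was 4.83e-05. Of further members, named after their values were seen, the STAT5 targets Cish and Socs2 had log2 fold changes of 2.43 and 2.30 (adjusted p = 0.043 and 0.00105). The prolactin receptor gene Prlr had 1.36 (adjusted p = 0.0438) and the leucine catabolism gene Ivd 1.99 (adjusted p = 5.37e-05). Socs3, Ghr, Stat5a and Stat5b did not pass (adjusted p from 0.645 to 0.999).

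Tph1, the rate-limiting enzyme of serotonin synthesis in islets, stood at 456 ± 121 CPM in STD KO libraries (SD, n = 3). It stood at 1.33 and 0.70 CPM in STD WT 1 and STD WT 2 but at 43.5 CPM in STD WT 3, and with that spread the difference did not pass (log2 fold change 4.91, SE 1.19, adjusted p = 0.0874). Without STD WT 3 the log2 fold change was 8.77 (SE 0.45, adjusted p = 1.06e-05). Over its 25 alternatives the adjusted p lay between 1.06e-05 and 0.441, past the threshold in 5. Of the 12 measured genes for serotonin synthesis, storage and receptors, only Tph2 passed among all genes, while Tph1 and Tph2 passed when adjusted over the list alone. The list had an adjusted p of 0.0505 by camera.

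Across all 16076 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 275 genes, of which 216 (78.5%) were higher and 59 lower in STD KO than in STD WT libraries. Of these, 215 differed by more than 2-fold. Several of the strongest increases were of genes almost silent in WT islets. Syt10, a synaptotagmin, had 514 counts over the KO libraries against 1 over the WT libraries, a ratio of 497 (95% counting interval 88.8 to 19700), and Lactbl1 had 405 against 2, a ratio of 196 (53.8 to 1620). Prok1, which encodes a secreted prokineticin, rose from 0.26 ± 0.31 to 20.5 ± 0.85 CPM (log2 fold change 6.28, SE 0.57, adjusted p = 0.000188). Malrd1 (5.91), the orphan receptor gene Gpr26 (5.84), the GABA-synthesising enzyme Gad2 (from 0.18 to 9.10 CPM) and the vesicle protein Rph3a (5.57) also rose, as did Kirrel3os (5.61), an antisense transcript whose reads cannot be told from those of its partner gene where the strand of counting is not stated. The largest decreases were smaller. Dapl1 fell from 37.6 ± 4.06 to 6.56 ± 2.37 CPM (SD, n = 3). Tmem179, Meltf, Rasd2, the cation channel gene Trpc4, Sgcz, the calcium sensor Vsnl1 and the opioid precursor Pdyn had log2 fold changes from −2.63 to −1.85. In the 12 fits that each left out 1 library, the call of Rasd2 was lost in 9 (adjusted p up to 0.195, without STD KO 3) and that of Pdyn in 2 (up to 0.0629, without STD KO 2).

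Hormone genes did not pass the threshold under the standard diet. Ins2 stood at 221937 ± 44134 CPM in WT and 150418 ± 39892 CPM in KO libraries, and Ins1 at 74697 ± 13139 and 72170 ± 19524 CPM (SD, n = 3). The log2 fold changes of Ins1 (−0.05), Ins2 (−0.56), Gcg (−0.48), Sst (−0.01), Ppy (−0.02), the beta cell transcription factor Mafa (0.00), the glucose transporter gene Slc2a2 (−0.48) and Aldh1a3 (−1.29) had adjusted p-values of at least 0.616. Ins1 and Ins2 are near-identical copies, so reads may have been split between them and their separate values are uncertain.

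Beyond the lactogen list, 5 of the 30 lists passed the set test under the standard diet, all with small medians and few called members. None of these 5 passed with fry (adjusted p from 0.445 to 0.577). Beta cell identity genes lay lower (median −0.17, camera adjusted p = 0.0021; 0.865 with an estimated correlation), and 1 of 28, the fatty acid receptor Ffar1, fell among all genes tested, against 3 lower adjusted over the list alone. Alpha cell genes lay lower (median −0.31, adjusted p = 0.0143; 0.825 with an estimated correlation), with 0 of 13 members called either way. Genes of the unfolded protein and integrated stress response lay higher (median 0.17, adjusted p = 0.00456; 0.825 with an estimated correlation), with Edem1, a factor of protein degradation in the endoplasmic reticulum, the 1 member of 25 that rose, over all genes and over the list alone. Interferon response genes lay higher (median 0.27, adjusted p = 0.00456; 0.825 with an estimated correlation), with Usp18 the 1 of 22 that rose by either adjustment. Macrophage and myeloid markers lay higher (median 0.34, adjusted p = 0.0021; 0.825 with an estimated correlation), with 0 of 22 called by either adjustment. Of the 12 fits without 1 library, the beta cell identity list lost its call in 1 (adjusted p = 0.23, without STD WT 3) and the alpha cell list in 2 (up to 0.198, without STD KO 3). The unfolded protein list lost its call in 1 (0.253, without STD KO 2) and the interferon list in 1 (0.0689, without STD KO 3). The myeloid and lactogen lists kept theirs in all 12. The calls of Ffar1 (lost in 9), Usp18 (8) and Edem1 (7 of the 12 fits without 1 library) were fragile, with adjusted p-values up to 0.221 without STD WT 2, 0.169 without STD WT 1 and 0.138 without STD WT 3. The other 24 lists had camera adjusted p-values from 0.0505 to 0.999, and the acinar list had a median of −0.12 but a test pointing up (adjusted p = 0.624). Single members of lists that did not pass also changed, among them Ehhadh and Chgb, which the lactogen list also holds. On the log2 scale Ehhadh of peroxisomal fatty acid oxidation rose by 1.83 (adjusted p = 0.000658), the cholesterol synthesis enzyme Dhcr7 by 0.91 (adjusted p = 0.00347) and the mitochondrial thioredoxin reductase Txnrd2 by 1.16 (adjusted p = 0.0163). The granule protein Chgb rose by 1.52 (adjusted p = 0.00868) and Ngfr by 3.59 (adjusted p = 0.000548), while the transcription factor gene Etv1 changed by −0.80 (adjusted p = 0.0368). Of these, Txnrd2, Chgb and Etv1 lost their calls in 4, 1 and 8 of the fits without 1 library (adjusted p up to 0.0953, 0.0671 and 0.158, each without STD WT 2).

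The count of 275 genes depended on single libraries: it was 146 without STD WT 2, 158 without STD KO 1 or STD KO 3 and 174 without STD KO 2, and DESeq2 called 474. On simulated counts with the spread of these libraries, 81 of 100 genes changed 4-fold were recovered but 29 of 100 changed 2-fold, so smaller changes were often not detectable.

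The second comparison asked the same question under the high fat diet, where 1189 genes passed the threshold, 627 (52.7%) higher and 562 lower in HFD KO than in HFD WT libraries. With the replicate number as a block in the high fat groups, 1969 passed, 910 higher and 1059 lower. The lactogen and STAT5 list again rose: 12 of 16 members were higher and none lower over all genes, against 13 higher and 2 lower adjusted over the list alone, with a median log2 fold change of 2.27 (camera adjusted p = 1.28e-13; 0.126 with an estimated correlation; fry 2.49e-05). Tph1 rose from 1.05 ± 0.21 to 892 ± 231 CPM (SD, n = 3; log2 fold change 9.71, SE 1.52, adjusted p = 0.00378 by edgeR). Gbp8 rose by 5.59 (SE 0.33, adjusted p = 4.07e-06), Tph2 by 5.49 (SE 0.60, adjusted p = 0.00046) and Neb by 5.21 (SE 0.51, adjusted p = 0.000229) on the log2 scale. Cish, Socs2 and Prlr, named after their values were seen, rose by 4.17, 3.04 and 1.82 (adjusted p = 0.00154, 0.000104 and 0.00378). Of the 12 serotonin genes, 2 rose, Tph1 and Tph2, over all genes and adjusted over the list alone, and the list as a whole had an adjusted p of 0.0883.

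Genes of lipid synthesis were lower in HFD KO islets. Of 23 cholesterol synthesis and uptake genes, 8 fell and none rose among all genes tested, while 13 were lower and 1 higher adjusted over the list alone (median log2 fold change −0.41). The sterol-regulated transcription factor gene Srebf2 fell from 161 to 73.5 CPM (log2 fold change −1.13, SE 0.22, edgeR adjusted p = 0.00931). The list passed with camera (adjusted p = 3.37e-07; 0.223 with an estimated correlation) and with fry (0.0013). Of 16 fatty acid synthesis genes, 5 fell and 1 rose, against 8 lower and 1 higher adjusted over the list alone (median −0.64, camera adjusted p = 0.000674; 0.592 with an estimated correlation). The fatty acid synthesis list did not pass with fry (adjusted p = 0.0696). The desaturase gene Scd2 fell from 136 ± 6.88 to 46.0 ± 18.2 CPM (SD, n = 3). The transcription factor genes Srebf1 and Mlxipl and the carboxylase Acaca had log2 fold changes of −1.10, −0.99 and −0.85 (adjusted p = 0.0136, 0.0213 and 0.0381). Acaca lost its call in 5 of the 12 fits without 1 library, Srebf1 and Mlxipl each in 3, with adjusted p-values up to 0.154 and 0.0779 without HFD KO 1 and 0.107 without HFD WT 3.

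**Figure D2:**
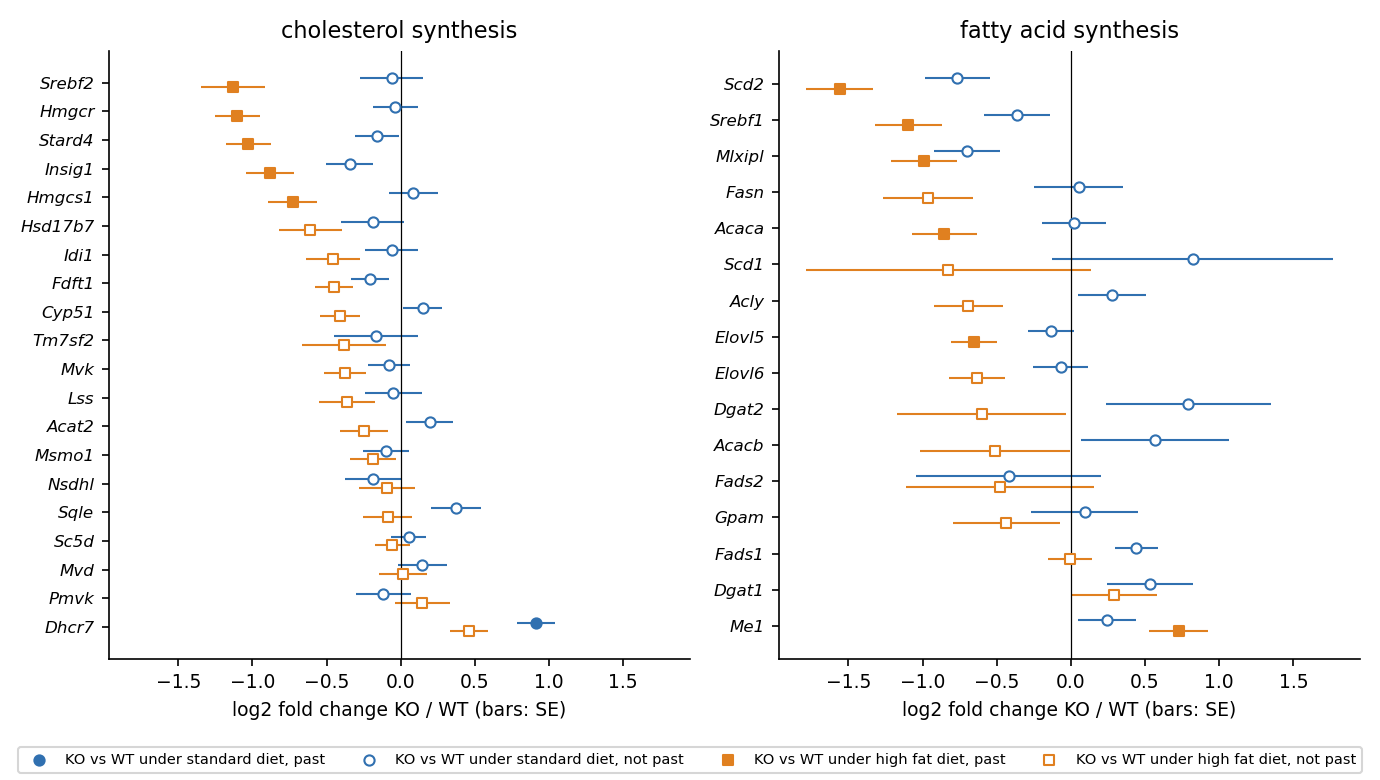
Log2 fold change between KO and WT libraries, with its SE, of genes of the cholesterol and fatty acid synthesis lists under the standard diet (circles) and the high fat diet (squares); filled symbols passed the threshold, and some list members are not drawn. Under the high fat diet 8 of 23 cholesterol genes and 5 of 16 fatty acid genes passed as lower, and under the standard diet 1 cholesterol gene, Dhcr7, passed, as higher.

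Beta cell identity genes were also lower under the high fat diet: 8 of 28 fell and 1 rose over all genes, against 15 and 1 adjusted over the list alone (median −0.52, camera adjusted p = 1.59e-06; 0.592 with an estimated correlation). The beta cell identity list did not pass with fry (adjusted p = 0.0696). The cation channel gene Trpm5 changed by −1.52 (SE 0.25, adjusted p = 0.0037) and Ffar1 by −1.33 (SE 0.18, adjusted p = 0.00111). The maturity marker Ucn3 changed by −1.13 (SE 0.19, adjusted p = 0.00459), while the proinsulin convertase gene Pcsk1 rose by 1.34 (SE 0.25, adjusted p = 0.00717). Slc2a2 stood at 691 ± 169 CPM in WT and 336 ± 91.5 CPM in KO (SD, n = 3), which did not pass (log2 fold change −1.04, edgeR adjusted p = 0.0521) but did with the replicate block in the high fat groups (−1.05, adjusted p = 0.0152). Mafa (−0.44, adjusted p = 0.169), Ins1 (0.58, adjusted p = 0.265), Ins2 (−0.31, adjusted p = 0.555), Gcg (0.36), Sst (0.05), Ppy (0.10) and Aldh1a3 (−0.17, the last 4 with adjusted p of at least 0.55) did not pass either. Among exocytosis and granule genes, Chgb, also in the lactogen list, rose by 2.16. The calcium channel gene Cacna1c (−1.24) and the priming factor Unc13a (−0.58) fell. Of 24 members 1 rose and 3 fell, against 3 and 8 adjusted over the list alone, and the list did not pass (adjusted p = 0.109). Unc13a lost its call in 5 of the fits without 1 library (adjusted p up to 0.133, without HFD KO 1).

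Stress and redox genes were higher in HFD KO islets. All 25 genes of the unfolded protein and integrated stress response had positive fold changes, of which 3 passed, Sdf2l1 (0.86), Dnajb11 (0.69) and Edem1 (0.64), and 12 passed adjusted over the list alone (median 0.57, camera adjusted p = 3.37e-07; 0.476 with an estimated correlation; fry 0.027). Of 22 antioxidant genes, 3 rose, Txnrd2 (1.44), Gpx1 (1.38) and Gpx3 (1.16), and 7 adjusted over the list alone (median 0.32, camera adjusted p = 0.0026; 0.476 with an estimated correlation; fry 0.027). The calls of Sdf2l1, Dnajb11 and Edem1 were lost in 8, 3 and 4 of the fits without 1 library and those of Gpx1 and Gpx3 each in 4, with adjusted p-values up to 0.202 (Sdf2l1, without HFD WT 3). Nuclear-encoded oxidative phosphorylation genes had a median of 0.49 (camera adjusted p = 3.37e-07; 0.752 with an estimated correlation), with 3 of 73 past the threshold over all genes and 2 over the list alone. Among them, Ndufa4 rose by 1.09 and Cox5a by 0.77 on the log2 scale. Their calls were lost in 5 and 11 of the 12 fits without 1 library (adjusted p up to 0.109 and 0.205, each without HFD WT 3). The genes of this list are short, with a median length of 763 bp against 1799 bp. Fold changes in this comparison fell with gene length across genes (rho −0.307), and with offsets corrected for length the list's median was 0.19. Without the library labelled HFD KO 2 it was 0.18. The cell cycle list had a median of 0.42 (camera adjusted p = 0.000268; 0.752 with an estimated correlation), with the mitotic kinase gene Aurka the 1 member of 30 called by either adjustment. Aurka lost its call in 3 of the fits without 1 library (adjusted p up to 0.0615, without HFD WT 3). Immediate early and heat shock genes had a median of 0.51 (adjusted p = 0.013; 0.752 with an estimated correlation) and 0 of 19 called members by either adjustment. The cell cycle call was lost without HFD WT 1 (adjusted p = 0.304), and that of the immediate early list without HFD KO 3 (0.173) or HFD WT 1. With fry, the oxidative phosphorylation (adjusted p = 0.266), cell cycle (0.279) and immediate early lists (0.266) did not pass.

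Markers of other cell types in the islet preparation moved as well. Myeloid markers were higher (median 0.43, camera adjusted p = 0.000512; 0.592 with an estimated correlation), with 4 of 22 rising, the macrophage receptor Mrc1 (2.42), C1qc (1.10), C1qb (1.01) and Fcer1g (0.89), and 7 adjusted over the list alone. Cytokine and NF-kappaB genes had a median of 1.09 (adjusted p = 0.000524; 0.592 with an estimated correlation), with Ccl2 higher and the interleukin receptor gene Il1r1 lower among 18, against 7 higher and 1 lower adjusted over the list alone. Stellate cell, fibroblast and matrix genes had a median of 0.995 (adjusted p = 0.000524; 0.597 with an estimated correlation), with Mgp the 1 of 20 past the threshold over all genes and 0 over the list alone. The calls of Mgp (lost in 9), Ccl2 (7), C1qc and Fcer1g (each 4) and Il1r1 (1 of the 12 fits) depended on single libraries, with adjusted p-values up to 0.15, 0.174, 0.114, 0.121 and 0.0517 without HFD KO 1 or HFD WT 3. HFD WT 1 stood apart in these lists: its mean log2 level relative to all 12 libraries was −1.13 for myeloid, −1.73 for cytokine, −1.75 for stellate cell and −2.56 for lymphocyte genes, while the stellate cell level of HFD KO 3 was 1.01. The myeloid call was lost without HFD WT 1 (adjusted p = 0.103) and the stellate cell call without HFD KO 3 (adjusted p = 0.102). None of the myeloid (adjusted p = 0.112), cytokine (0.139) and stellate cell (0.166) lists passed with fry. The lymphocyte list, with 0 of 14 members called by either adjustment, had a median and mean of −0.57 but a test pointing up (adjusted p = 0.874).

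The remaining lists did not pass the set test between HFD KO and HFD WT libraries. Their camera adjusted p-values were 0.809 for alpha cell, 0.106 for delta, PP and epsilon cell, 0.0822 for beta cell dedifferentiation and disallowed genes, 0.707 for mitochondrially encoded mRNAs, 0.553 for the tricarboxylic acid cycle and pyruvate entry, 0.367 for fatty acid oxidation and 0.809 for glycolysis and hypoxia. They were 0.145 for interferon response, 0.139 for acinar cell, 0.565 for ductal cell, 0.361 for endothelial cell, 0.679 for adipocyte, 0.361 for Schwann cell and neuron, and 0.653 for erythrocyte. The glycolysis list had a median of −0.05, a mean of 0.05 and a test pointing up. The alpha cell list had a median of 0.09, a mean of −0.06 and a test pointing down, and the ductal list a median of −0.18, a mean of 0.15 and a test pointing up. Called members of these lists included Ehhadh (2.07), which the lactogen list also holds, and Ngfr (2.86) as higher. Those called as lower included Ppargc1a (−1.56), Etv1 (−0.92), Slc7a2 (−1.20) and Th (−1.33). Of these, Slc7a2 and Th each lost their calls in 4 of the fits without 1 library (adjusted p up to 0.065 without HFD WT 3 and 0.091 without HFD KO 1). Adjusted over the list alone, at most 1 member of any of these lists was higher and at most 2 were lower.

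The largest single changes under the high fat diet overlapped with those under the standard diet. Gpr26, Gstt4 and Lactbl1 had no count in any HFD WT library and were at least 537-fold, 121-fold and 94.9-fold higher in HFD KO libraries, taking a floor of 3 counts over the group (0.0567 CPM). Prok1 had 878 counts against 2, a ratio of 453 (95% counting interval 125 to 3750), Gbp11 472 against 1, a ratio of 487 (87.0 to 19300), and Syt10 357 against 1, a ratio of 368 (65.7 to 14600). Lrrc55 rose from 0.11 ± 0.10 to 46.5 ± 6.70 CPM (SD, n = 3). Gbp8 and Gbp11 belong to a family of similar genes on chromosome 5, so reads may have been shared between its members. Among the decreases, Tmem179 fell from 19.1 ± 9.59 to 1.89 ± 0.50 CPM, the LIM homeobox gene Lmx1b from 10.7 ± 2.20 to 1.75 ± 0.35 CPM and the matrix glycoprotein gene Tnr from 261 ± 74.9 to 53.3 ± 18.4 CPM (SD, n = 3), and Lancl3, Rasd2, Sgcz and Dok7 had log2 fold changes from −2.53 to −2.38. Rasd2 lost its call in 2 of the fits without 1 library (adjusted p up to 0.0659, without HFD KO 1).

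The count under the high fat diet depended strongly on single libraries: it was 519 without HFD KO 1, 524 without HFD WT 3, 744 without HFD WT 1 and 759 without the library labelled HFD KO 2, but 2899 without HFD KO 3. DESeq2 called 1845 genes, a fit of these groups alone 543, and a test of log2(FPKM + 1) put 64.5% of its calls on the higher side. With offsets corrected for gene length 1345 genes passed, of which 1070 were among the 1189 of the main fit. After this correction the cholesterol list still passed camera as lower (adjusted p = 1.5e-07). Such results of the lists other than cholesterol and oxidative phosphorylation are not reported here.

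The genotype effects under both diets were then compared gene by gene. Of the 275 genes called under the standard diet, 251 were also called under the high fat diet, all in the same direction. Of these, 202 were higher and 49 lower, where independent lists of those sizes would share 8.4 and 2.1. All 275 had the same sign under the high fat diet, with a median absolute log2 fold change of 1.83 under the standard and 2.07 under the high fat diet. Over all 16076 genes the fold changes correlated with Pearson r = 0.544 and Spearman rho = 0.336 across genes, which are not independent replicates. Each gene's spread came from 1 fit of all 12 libraries, and without HFD WT 3 the standard diet count was 218. The lists of calls were therefore not independent, and the expected 8.4 and 2.1 are only a rough reference. The comparisons shared no libraries in their group means. No gene passed edgeR's test of the difference between them (0 of 16076; 1271 at an unadjusted p under 0.05; 23 called by DESeq2), so the larger count under the high fat diet was not shown to be a difference between diets.

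**Figure D3:**
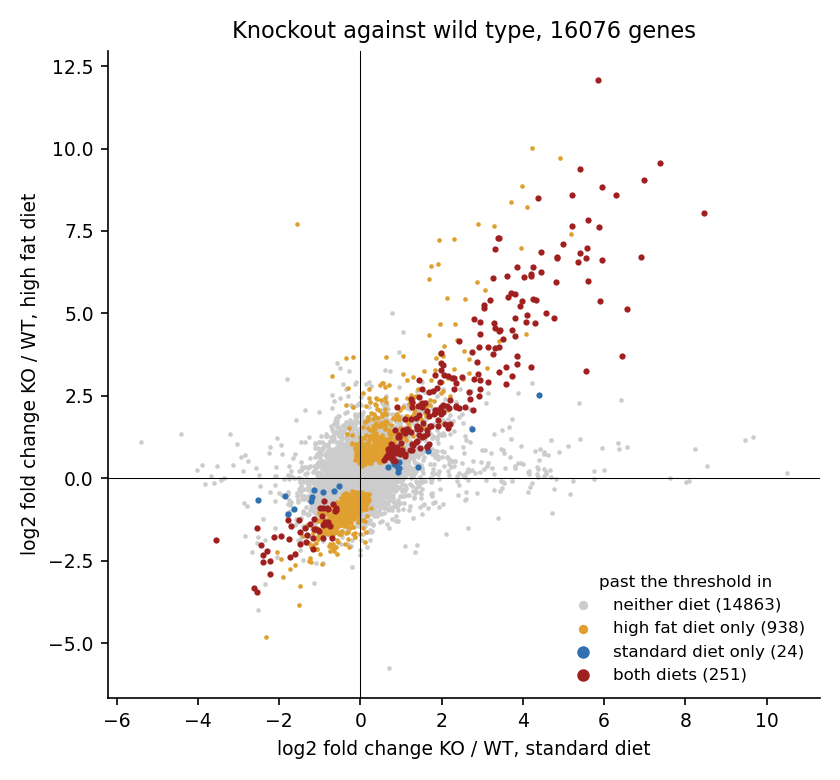
Log2 fold change between KO and WT libraries of each of 16076 genes under the standard diet (horizontal axis) and the high fat diet (vertical axis), coloured by where the gene passed the threshold. The 251 genes called in both comparisons all lie in the quadrants of equal sign, 202 higher and 49 lower in KO.

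**Figure D4:**
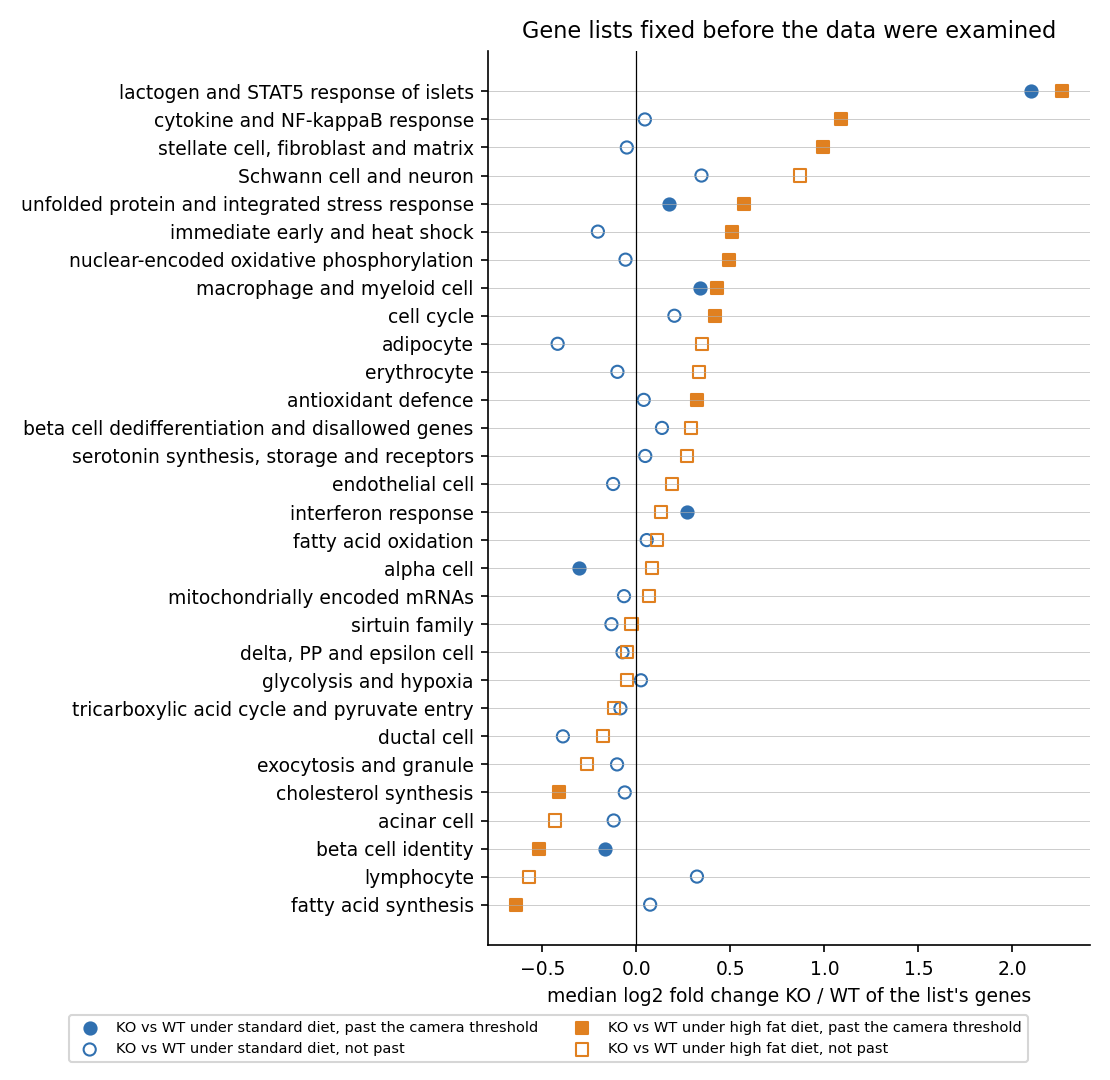
Median log2 fold change between KO and WT libraries of the 30 gene lists under the standard diet (circles) and the high fat diet (squares); filled symbols passed the set test with the preset correlation. The lactogen and STAT5 list has the highest median under both diets, 2.10 and 2.27. With an estimated correlation it was the only list past the threshold under the standard diet, against 0 lists under the high fat diet.

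The third comparison asked what the high fat diet changed in WT islets. No gene passed the threshold with edgeR's quasi-likelihood test (0 of 16076; 762 genes at an unadjusted p under 0.05), while DESeq2 called 45, 5 higher and 40 lower. Gfra3 (−1.67) and Peg10 (−1.65) had an adjusted p of 0.436, and Hdac6 (0.64), Nmnat2 (1.03) and Lrpprc (0.59) had 0.551. The hormone genes and Sirt3 (0.03) had adjusted p-values of 1.

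As groups, 16 lists passed camera in WT islets, 6 up and 10 down, but none did with an estimated correlation or with fry. With the replicate block in the high fat groups the exocytosis and granule list also passed, as higher (adjusted p = 0.0255 against 0.0799). All 19 immediate early and heat shock genes were lower with the high fat diet (median −0.90, camera adjusted p = 6e-19; 0.138 with an estimated correlation), among them Btg2 (−1.32) and Fos (−1.22, from 1160 to 498 CPM). Of these, 0 passed among all genes and 9 adjusted over the list alone. Cytokine and NF-kappaB genes had a median of −1.41 (adjusted p = 6.73e-10; 0.324 with an estimated correlation), with 0 called and 3 lower adjusted over the list alone. Stellate cell, fibroblast and matrix genes had a median of −0.78 (adjusted p = 1.99e-09; 0.34 with an estimated correlation) and alpha cell genes −0.41 (adjusted p = 2.28e-06; 0.138 with an estimated correlation), with 0 called in both, and 0 and 4 lower adjusted over the list alone. Cholesterol synthesis genes had a median of 0.15 (adjusted p = 0.000392; 0.34 with an estimated correlation), with 0 of 23 called by either adjustment. These 5 lists kept their calls in each of the 12 fits without 1 library. HFD WT 1 had the lowest level of the 12 libraries in the immediate early (−0.89), cytokine (−1.73) and stellate cell (−1.75) lists. The other 11 lists lost their call or turned in at least 1 of those fits: the lactogen list, with a median of −0.50 (adjusted p = 0.00231; 0.518 with an estimated correlation), had 0.155 without STD WT 3, the ductal list turned up without STD WT 1 (0.538), and the acinar list turned down without STD WT 3 (0.135).

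The same diet comparison in KO islets gave 7 genes, 5 higher and 2 lower in HFD KO than in STD KO libraries (2010 genes at an unadjusted p under 0.05; 116 called by DESeq2). The chloride channel gene Ttyh1 rose from 14.2 to 83.0 CPM (log2 fold change 2.55, SE 0.29), Serpina7 rose by 2.51 (SE 0.33), Pdyn by 2.38 (SE 0.32), the scaffold gene Dlg2 by 1.49 (SE 0.19) and the elongation factor gene Eef1a2 by 1.11 (SE 0.16). The potassium channel gene Kcnj12 changed by −1.86 (SE 0.25) and the G protein gene Gnai1 by −0.90 (SE 0.12). The edgeR adjusted p was 0.04 for Eef1a2 and 0.032 for the other 6. With the replicate block in the high fat groups Eef1a2 and Kcnj12 did not pass (adjusted p = 0.0706 and 0.0625). The diet effects of both genotypes had a correlation of r = 0.092 and rho = −0.025 across genes, and 5 of the 7 genes had the same sign in WT.

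Of the lists, 9 passed camera between HFD KO and STD KO libraries, none with an estimated correlation and 1 with fry. With the replicate block in the high fat groups the lymphocyte list also passed, as lower (adjusted p = 9.79e-05 against 0.0871). The nuclear-encoded oxidative phosphorylation list was higher (median 0.52, adjusted p = 3.35e-20; 0.682 with an estimated correlation), with 0 of 73 called and 1 adjusted over the list alone. Fold changes again fell with gene length (rho −0.339), and with length-corrected offsets its median was 0.27. Without the library labelled HFD KO 2 the median was also 0.27. Cholesterol synthesis genes were lower (median −0.26, adjusted p = 4.43e-07; 0.429 with an estimated correlation; fry 0.0475), with 0 of 23 called and 7 adjusted over the list alone, as were fatty acid synthesis genes (median −0.51, adjusted p = 2.42e-05; 0.682 with an estimated correlation), with 0 of 16 called and 2 adjusted over the list alone. These 3 lists kept their calls in every fit without 1 library, and the other 6 did not. The 7 gene calls were fragile: 0 genes passed without any 1 of STD WT 2, HFD WT 1, HFD WT 3 or the STD KO libraries, 1 without STD WT 1, HFD KO 1 or the library labelled HFD KO 2, 2 without STD WT 3, and 801 without HFD KO 3.

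The last comparison was the interaction, whether the genotype effect differed between diets. No gene passed with edgeR's quasi-likelihood test (0 of 16076; smallest adjusted p 0.157; 1271 at an unadjusted p under 0.05), while DESeq2 called 23, 16 higher and 7 lower. The smallest p-values belonged to Eef1a2 (1.67, SE 0.22, adjusted p = 0.157), Dlg2 (1.72), Hdac6 (−1.12, both adjusted p = 0.306), Ttyh1 (2.32), Cabp7 (−1.51, both 0.376) and the calcium release channel gene Itpr2 (−1.12, 0.414). Sirt3 had an interaction of 0.44 (SE 0.32, adjusted p = 0.672) and Tph1 of 4.81 (SE 1.64, adjusted p = 0.621), which fell to 0.95 (SE 0.49) without STD WT 3. In the simulated counts for this comparison 53 of 100 genes changed 4-fold and 5 of 100 changed 2-fold were recovered, so a difference of that smaller size was mostly not detectable. As groups, 12 lists passed camera, 8 up and 4 down, and none with an estimated correlation (adjusted p from 0.182 to 0.884). Of the 12, 5 kept their calls in every fit without 1 library. With the replicate block in the high fat groups the acinar call was lost (adjusted p = 0.12) and the lymphocyte list passed as lower (0.00646).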

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

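No result here was singled out by a sample far from its group, because groups of 3 are too small for that test, and no deposited data were left unused. What singled out the following lists was a difference between the genotype effects under the 2 diets, tested as the interaction with camera. The set tests and the fits without 1 library were planned. The tests of explanations below were chosen only after the result was seen, except the label splits of KO against WT under each diet and of the diets in KO.

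Lists whose genotype effect lay higher under the high fat diet had median log2 interactions of 0.527 for nuclear-encoded oxidative phosphorylation (camera adjusted p = 8.46e-11), 1.352 for cytokine and NF-kappaB response (5.6e-06), 1.059 for stellate cell, fibroblast and matrix (9.31e-05) and 0.314 for the unfolded protein and integrated stress response (0.000842). The others were 0.793 for immediate early and heat shock (0.00458), 0.691 for the lactogen and STAT5 response (0.00466), 0.233 for cell cycle (0.00498) and 0.201 for antioxidant defence (0.0461). Lower were cholesterol synthesis (−0.442, adjusted p = 8.96e-10), fatty acid synthesis (−0.648, 5.29e-05), beta cell identity (−0.258, 0.00175) and acinar cell (−0.339, 0.049). None of the 12 passed with an estimated correlation (adjusted p from 0.182 for cholesterol synthesis to 0.884 for acinar cell), and fry passed cholesterol synthesis alone (0.0316). No single gene passed edgeR's interaction test (0 of 16076; 1271 at an unadjusted p under 0.05; DESeq2 23), and adjusted over the list alone 8 cholesterol genes were lower. The oxidative phosphorylation median was 0.233 without the library labelled HFD KO 2 and 0.241 with length-corrected offsets.

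Of the 12 lists, 5 kept their calls in every fit without 1 library: oxidative phosphorylation, cholesterol synthesis, cytokine, fatty acid synthesis and the unfolded protein list. The stellate cell list lost its call in 1 fit (adjusted p = 0.0853, without HFD KO 3). The beta cell identity list lost it in 2 (up to 0.139, without STD WT 1), and the immediate early and lactogen lists each in 2 (up to 0.106 and 0.102, without HFD KO 3). The cell cycle list lost it in 4 and pointed down without HFD WT 1 (0.843). The antioxidant list lost it in 6 (up to 0.147, without HFD WT 2). The acinar list lost it in 7 (up to 0.525, without STD KO 3) and pointed up without STD WT 3 (0.0897).

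The lactogen and STAT5 list was higher in KO libraries under both diets. A shift among the 11 other cell types with a list is argued against. The bootstrap interval of the lactogen list's median was 0.986 to 3.635 under the standard and 1.521 to 4.937 under the high fat diet. This lay above the largest median of those lists, 0.346 (Schwann cell and neuron) and 0.995 (stellate cell, fibroblast and matrix). The bootstrap treats genes as independent. A change in a subset of beta cells, or in cells without a list, was not tested. Signalling by a lactogenic hormone stays open: the 11 of 16 members past the threshold and higher under the standard diet and 12 under the high fat diet restate the pattern and decide nothing. A growth hormone minigene, which some Cre driver lines carry, may give the same signal without any role of Sirt3; over the 6 KO libraries the list level did not follow Sirt3 (r = −0.189, exact permutation p = 0.814), which 6 libraries are too few to decide. The labels name no Cre line and hold no group with Cre alone, so loss of Sirt3 and the driver cannot be told apart.

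For 12 genes raised in KO libraries, STD WT 3 lay between WT and KO. Their mean in STD WT 1 and STD WT 2 was under 5% of the KO level. This limit used the same 2 libraries as the baseline, which favours higher values in STD WT 3. Against STD WT 1 and STD WT 2, STD WT 3 lay a median of 5.39% of the way to the KO level (0.5% to 11.56% over the genes). Medians over these genes of the other 5 WT libraries, each against the remaining 4, were −0.37% to 0.49%. The STAT5 targets Cish and Socs2, which that limit left out, lay 30.02% and 18.5% of the way. RNA from KO islets mixed into this library would give 1 share for all genes; the log2 SD of shares was 0.739, against at most 0.516 in single KO libraries, but 0.358 against 0.489 without Gm13716, so the test rests on 1 gene with 5 counts. A weak lactogen signal in these islets would raise lactogen genes more; their median share was 1.44 points above that of the other genes (permutation p = 0.495 over genes). Without the limit on the WT level, 8 lactogen genes lay a median of 7.92% and 23 others 4.7% of the way. The p-value depended on the test and the fold limit: it was 0.0232 by rank sum and 0.053 by permutation with these 31 genes, and 0.186 and 0.153 with 72 genes at a lower limit. The mean squared deviation of the 31 genes from 1 share, relative to the spread between WT libraries, was 4.05, inside the 0.58 to 8.31 of the other WT libraries. The higher shares of Cish and Socs2 go against 1 share alone, but they are 2 genes picked after their values were seen. These explanations therefore cannot be told apart.

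The oxidative phosphorylation list was higher in HFD KO than in HFD WT libraries. Whether a trend with gene length is the whole cause stays open. The median of 0.492 lay at percentile 99.99 of 10000 random lists matched on length and expression (median 0.297, central range 0.19 to 0.38), which ignore correlation between genes, and length-corrected offsets left 0.187 (camera adjusted p = 0.00628). With the replicate block in the high fat groups the percentile was 99.56, and length-corrected offsets left 0.178 (adjusted p = 0.00332). With an estimated correlation the list did not pass before (adjusted p = 0.752) or after the length correction (0.785; 0.729 with the block), so the spread between libraries does not let these values exclude the trend. Without the library labelled HFD KO 2 the median was 0.176 (adjusted p = 0.0134), so how far that library alone makes the pattern stays open. For high fat against standard diet in KO, the split of STD KO 1, STD KO 3 and HFD KO 3 against the others called 1437 genes where the real split called 7, which points to a structure of the samples; with length-corrected offsets it called 0 and the real split 6, so a length trend may be that structure.

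Other splits of the same libraries were too few, at 10 per comparison of 2 groups, for a share under 0.05. KO against WT called 275 genes under the standard and 1189 under the high fat diet, the highest other split 0 in both, so 1 of 10 splits, the real one, was as large. Under the high fat diet, 4 of the 10 splits part all 3 same-numbered pairs, the real one among them, and the other 6 part 1 pair. For diet in WT, 10 of 10 splits were as large as the real one (0 genes with edgeR, 762 at an unadjusted p under 0.05, 45 with DESeq2; highest other 1), and for diet in KO 2 of 10 (7 genes; highest other 1437). For the interaction, 100 of 100 splits were as large as the real one (0 genes with edgeR, 1271 at an unadjusted p under 0.05, 23 with DESeq2; highest other 1249). Where the real count is 0, every split is as large by construction, so these shares decide nothing for the interaction or for diet in WT. The splits for the interaction could exchange the WT and KO labels under 1 diet alone. The tested difference then holds the sum of the genotype effects, so the split with 1249 genes need not mark another structure of the samples.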

How the results depend on the processing

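Leaving out STD WT 3 and HFD KO 2 together, the length-corrected offsets and the replicate block in the high fat groups alone were chosen after seeing the data; the other alternatives were planned. Of 9490 values of named genes under alternatives, 8992 kept their side of the threshold, 131 passed only under the alternative and 367 no longer passed. The sign changed in 127, of which 0 passed the threshold in either fit. These values cover 384 pairs of gene and contrast, most of which had not passed in the main fit. The 8992 therefore do not show how stable the calls were. For KO against WT, 8 of 29 calls of named genes under the standard diet were lost in some fit that left out a single library. Under the high fat diet 25 of 60 were lost in this way, and for diet in KO 7 of 7.

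DESeq2 called 474 and 1845 genes for KO against WT under the standard and high fat diets, 45 and 116 for diet in WT and KO, and 23 for the interaction, against 275, 1189, 0, 7 and 0 with edgeR. With DESeq2 size factors edgeR called 276, 1208, 0, 7 and 0, so the size factors were not the cause. The other parts of the DESeq2 test were not tested apart. With only the 2 groups compared, which has fewer samples to estimate spread, the high fat comparison of genotypes gave 543 and diet in KO 0. Without STD WT 3 and HFD KO 2 these gave 745 and 2, and with length-corrected offsets and HFD KO 3 left out 2246 and 455; the cause was not tested. For diet in KO, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) gave 2 and 3 genes, and for the interaction no filter on low counts gave 1; the cause was not tested. On FPKM 88.2% and 64.5% of calls for KO against WT were higher, against 78.5% and 52.7% on counts, and the median of all genes was 0.103 under the standard diet, against −0.017 on counts. It was −0.166 against −0.025 for diet in KO and −0.109 against 0.01 for the interaction. Unlike the counts, the FPKM were not scaled by TMM. The TMM factors were 1.107, 1.017 and 1.142 in STD KO and 1.061, 0.962 and 0.953 in STD WT libraries. Leaving them out moves all fold changes of that comparison upward. Under the high fat diet the median of all genes was 0.002 on FPKM against −0.002 on counts. Such a shift is therefore not shown for the 64.5%, and its cause was not tested.

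With an estimated inter-gene correlation, 1, 0, 0, 0 and 0 lists passed in the 5 contrasts, and with fry 1, 4, 0, 1 and 1, against 6, 12, 16, 9 and 12 with camera's preset of 0.01; the cause was not tested for fry. The correlation of the genotype effects between diets, 0.544, was 0.219 with DESeq2 and 0.172 with no filter on low counts, both over 29339 genes. With the stricter filter, over 14269 genes, it was 0.628. Within edgeR it thus rose as more genes with low counts were left out. Whether this alone explains the value with DESeq2 was not tested.

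Leaving out each library in turn gave 146 (without STD WT 2) to 296 (without HFD WT 2) genes for KO against WT under the standard diet, 519 (without HFD KO 1) to 2899 (without HFD KO 3) under the high fat diet, and 0 to 801 (without HFD KO 3) for diet in KO. Diet in WT and the interaction stayed at 0 with edgeR. Lists past the threshold numbered 6 to 11, 11 to 16, 12 to 17, 6 to 14 and 9 to 14. The correlation of the genotype effects was 0.357 to 0.597, and that of the diet effects 0 (without HFD KO 1) to 0.236 (without STD KO 3). The log2 fold change of Sirt3 was −0.90 to −0.73 under the standard and −0.63 to −0.15 under the high fat diet. A lone pair left in a group was assumed to vary like the others.

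The labels number the replicates of each group alike but do not say that equal numbers belong together. Of 18 same-numbered pairs over all groups, 4 correlated above 0.1, 3 of them between HFD WT and HFD KO. Differently numbered pairs reached r = 0.518, and their median was −0.001, against −0.048 for same numbers. A replicate block over all 12 libraries gave 243, 1343 (627 higher, 716 lower), 0, 0 and 0 genes in the 5 contrasts. The block in the high fat groups alone gave 321, 1969, 0, 9 and 0, and with length-corrected offsets 353, 1867, 0, 12 and 0; the cause was not tested. Between HFD KO and HFD WT it added the calls of Slc2a2, Cd302 and Cldn5 (adjusted p = 0.0152, 0.0441 and 0.0271) and changed no other call reported here.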

Other observations

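The following values and the test were chosen after the data were seen. The ratio of Ins1 to Ins2 counts was higher in KO libraries: 0.33 ± 0.012 in 6 WT and 0.535 ± 0.078 in 6 KO libraries (SD), with WT from 0.318 to 0.351 and KO from 0.46 to 0.66. By group it was 0.338 in STD WT, 0.48 in STD KO, 0.322 in HFD WT and 0.591 in HFD KO. An exact permutation of genotype within diets gave p = 0.005, the smallest that 400 permutations can give. Reads shared between these near-identical genes make the ratio itself uncertain.

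Some genes stood far apart between libraries of 1 group. STD KO 3 had 53.3 CPM of the mucin gene Muc2 and 104 CPM of Clca1, against at most 1.92 and 6.43 CPM in the other 11 libraries. Fabp2 stood at 28.43 CPM in HFD KO 1, 13.77 CPM in STD KO 3 and 13.35 CPM in HFD WT 1, and at most 0.93 CPM elsewhere. The B cell genes Cd79b and Ms4a1 were highest in HFD WT 2 (87.8 and 86.2 CPM) and the library labelled HFD KO 2 (62.2 and 70.1 CPM) and lowest in HFD WT 1 (2.68 and 2.47 CPM). All samples were labelled as 40 weeks old, although the labels give HFD KO animals 5 to 6 weeks of standard food before 36 weeks of high fat food.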
